A study of Rattus norvegicus with 36 samples.

How the data were processed

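Gene expression was measured by RNA sequencing in rat precision-cut lung slices, thin living sections of lung kept in culture. The 36 libraries fall into 6 groups of 6: untreated slices at the labelled time 0, untreated slices at the labelled time 72, slices with TGFb at 72, and slices with TGFb and Pirf, Nint or Sora at 72. The labels carry no unit for time and no dose. Pirf, Nint and Sora are read here as pirfenidone, nintedanib and sorafenib, from knowledge of the study. Groups and replicate numbers were taken from the sample titles. No label says whether the 6 replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

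Per the labels' protocols, total RNA was extracted with an RNeasy 96 kit, and stranded total RNA libraries were made after removal of ribosomal RNA. Per the submitters' processing notes, RSEM and edgeR were used with the genome build Rnor_6.0. The aligner, the annotation release and the strand setting are not given in the sources used here. The first deposited table holds the authors' expected counts per gene, as RSEM estimates them, with no scaling for depth or gene length. It lists 32883 Ensembl gene IDs, of which 7569 had a total of 0, and 8.59% of its values were not whole numbers. RSEM can share a read among genes with near-identical sequence, so counts of such genes are uncertain. The second deposited table holds the authors' log2 CPM values for 14984 genes that its name describes as expressed and protein coding. These values were checked against the count table and equalled edgeR's log2 CPM with TMM (trimmed mean of M values) factors and a prior count of 0.25, to within 5e-14. This table is called the coding table here.

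The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 15644 genes, 14480 of them in the coding table and 1164 outside it. TMM scaling factors were applied, and all 36 libraries entered one quasi-likelihood fit with a mean per group and no covariate, so that the groups shared one dispersion trend. Each comparison was a contrast tested with glmQLFTest, with Benjamini-Hochberg adjustment over the 15644 genes. A gene was called at an adjusted p under 0.05, and every adjusted p in the text comes from this test unless another tool is named. Fold changes are thus relative to the TMM scaling. SE is the absolute log2 fold change divided by the square root of its F statistic. Normalized counts are TMM-scaled counts at the mean library size. Principal components were computed from log2 CPM with a prior count of 2.

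The comparisons were untreated slices at 72 against 0, TGFb against untreated at 72, each drug with TGFb against TGFb alone, and the drugs against each other. A gene called for TGFb was counted as reversed by a drug when it was called in the opposite direction in the drug comparison. The TGFb-alone libraries enter both comparisons with opposite signs, so chance alone favours reversal. There were 3 checks of this. In 20 simulations the residuals of the time-72 libraries were reassigned at random around group means in which TGFb acted and no drug did. The overlap of independent lists (the product of the 2 numbers of calls divided by the genes tested) was computed per direction. The 6 TGFb-alone libraries were also split into 3 and 3 in all 20 ways, with one set of 3 used for the TGFb comparison and the other for the drug.

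The share of the TGFb change that a drug removed was computed after the data were examined. Genes were chosen by their TGFb call in 3 TGFb-alone and 3 untreated libraries, and the share was measured against the other 3 and 3, over 40 such choices. It is the mean log2 difference between TGFb alone and a drug library, in the TGFb direction, as a percentage of the mean TGFb change in the same held-out libraries. Comparisons of this share, and of library measures, used two-sided exact permutation tests of 6 against 6 libraries.

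The count table has no gene names, and the reference gene table at hand carries no Ensembl IDs, so 0 of the 15644 tested IDs could be paired with a name. For this reason 39 gene lists that had been fixed before the data were examined, their camera tests, the genes fixed by name, and checks of gene length or GC content were not run. The rule fixed before the data were examined for naming genes was applied to IDs. In each of the 5 comparisons other than drug against drug, it took the highest and lowest log2 fold changes among called genes whose groups of 6 did not overlap and whose mean normalized count was at least 50 in the higher group. No more than 2 IDs that rose and 2 that fell are given per comparison, fewer than the rule allows. For genes reversed by all 3 drugs, the 2 risen and 2 fallen IDs with the largest TGFb change are given, with no minimum count and no rule on overlap. Chance separates the 2 groups of 6 for 0.22% of genes.

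Total counts per library ranged from 15886927 to 32932981. Where every library of a group was at 0, the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts it is a ratio with an exact 95% interval. Both cover counting error only. No 2 libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between raw counts was 13.1 to 179 over the 90 pairs. The procedure was tested on simulated counts for the TGFb comparison over 15485 genes, of which 200 were changed. There edgeR called 71% of genes changed 1.5-fold and 94% of genes changed 3-fold in the right direction, and 3.51% of its calls were false. The simulated counts were drawn independently for each gene, without differences that many genes of a library share, so these rates need not hold for the real libraries.

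Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, no low-count filter, a filter of 50 counts in 6 libraries, the coding table's genes only, a separate fit of the 12 libraries of each comparison, the replicate number as a block, DESeq2's own test, limma 3.58.1 on the deposited log2 CPM, a test against a fold of 1.2, leaving out each library, and the split of the TGFb-alone libraries. Alternatives added afterwards were total counts without scaling factors, libraries thinned at random to one common total below the lowest, the scaling factor as a covariate, and the time-0 comparison without replicates 1 and 3.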

Results

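RNA was sequenced from rat precision-cut lung slices, with the stated purpose of characterizing a slice model for testing anti-fibrotic drugs. TGFb, a growth factor that drives fibrosis, was given alone or together with Pirf, Nint or Sora, and there were 6 libraries in each of 6 groups. Total counts per library lay between 15886927 and 23255533 at time 0 and between 18971526 and 32932981 at time 72. Expression in these libraries was compared over 15644 genes. For each ID chosen for a comparison, all 6 libraries of the higher group exceeded all 6 of the lower, which was not required of IDs chosen as reversed by all 3 drugs.

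The first principal component held 43.4% of the variance and separated the time-0 libraries, with scores of 87.5 to 131.6, from all libraries at 72, whose scores lay below 0. The second component held 13% and set the Pirf libraries apart, with scores of 39.6 to 64.1, whereas no other library exceeded 32. The Nint libraries lay among or beside those with TGFb alone on both axes. Group means of the first component were -38.2 ± 3.52 (SD, n = 6) for TGFb alone, -36.9 ± 2.66 for Nint, -26.6 ± 2.5 for Sora, -8.12 ± 3.37 for Pirf and -10.3 ± 3.42 for untreated slices at 72. The share of counts from genes outside the coding table was 13.6% ± 0.729 with Pirf and 11.7% ± 0.673 with TGFb alone (exact permutation p = 0.0043, adjusted p = 0.064 over 15 library tests), a difference that failed the correction. TMM scaling factors averaged 1.07 ± 0.00884 with Pirf, 1.03 ± 0.0433 with Sora, 0.964 ± 0.051 with TGFb alone and 0.967 ± 0.0275 with Nint.

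**Figure D1:**
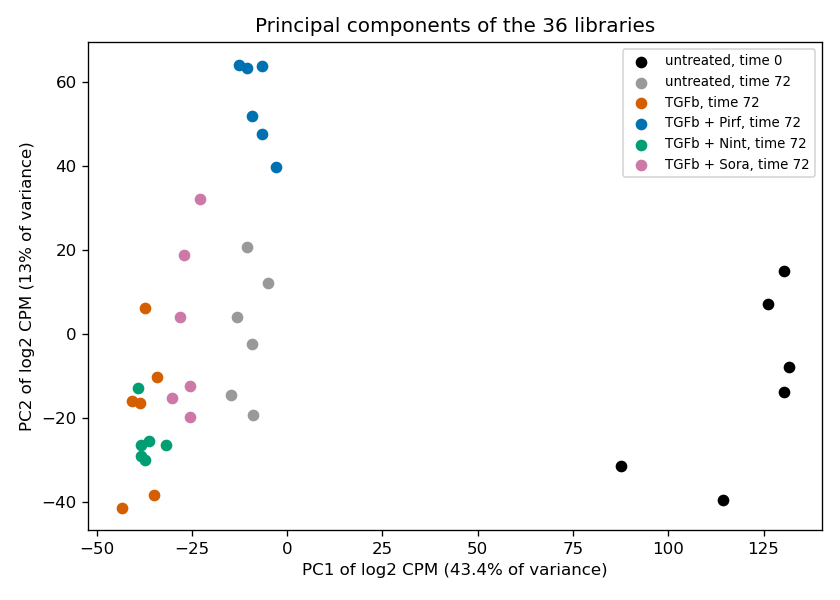
Each point is one of the 36 libraries, placed by its scores on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group. The time-0 libraries lie at the right, at 87.5 or above, and the Pirf libraries at the top, at 39.6 or above.

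Untreated slices at 72 were compared with those at 0 to describe what changed without any treatment. ENSRNOG00000007509 rose from 3.15 ± 5.19 normalized counts at time 0 to 311 ± 102 at 72 (SD, n = 6), a log2 fold change of 6.68 (SE 0.57, adjusted p = 1.96e-12). ENSRNOG00000006926 rose from 24.6 ± 41.9 to 1334 ± 452 (log2 fold change 5.84, SE 0.49, adjusted p = 1.48e-12). In both, replicate 3 at time 0 stood above the other 5, at 13.4 and 109.9. ENSRNOG00000058357 had 467 ± 84.3 normalized counts at time 0 and 0 counts in all 6 libraries at 72, at least 884-fold lower against the floor of 3 counts over the group (adjusted p = 4.7e-08). ENSRNOG00000019500 fell from 17460.2 ± 5648 to 16.5 ± 6.84 (log2 fold change -10.07, SE 0.32, adjusted p = 3.65e-23), and replicate 1 at time 0 stood below the other 5, at 6734.

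In that comparison 11454 genes (73.2%) were called, of which 5938 rose and 5516 fell. Of the called genes, 4295 changed at least 2-fold. Of the 1164 tested genes outside the coding table, 201 rose and 423 fell.

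TGFb alone was compared with untreated slices at 72 to describe the response to the growth factor. ENSRNOG00000003776 rose from 1.4 ± 0.918 to 66.7 ± 30.6 normalized counts (log2 fold change 5.45, SE 0.61, adjusted p = 2.92e-08). ENSRNOG00000011824 rose from 42.3 ± 16.7 to 1218 ± 726 (log2 fold change 4.83, SE 0.41, adjusted p = 1.72e-10). Replicate 3 with TGFb held 2679.5 counts of it, and the other 5 held 774.6 to 1101. ENSRNOG00000023870 fell from 109.8 ± 35.6 to 3.89 ± 2.25 (log2 fold change -4.77, SE 0.52, adjusted p = 1.84e-08). ENSRNOG00000003888 fell from 157 ± 61.4 to 6.06 ± 3.24 (log2 fold change -4.64, SE 0.6, adjusted p = 3.89e-07). Both IDs that rose had lower levels at 72 than at 0 without treatment, with log2 fold changes of -4.22 and -2.02 (adjusted p = 3.79e-07 and 3.93e-05).

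TGFb changed 4130 genes (26.4%), of which 2187 rose and 1943 fell. At least 2-fold changes were seen in 475 genes that rose and 566 that fell. Without scaling factors, on total counts alone, 1363 rose and 2543 fell. A test against a fold of 1.2 called 1779 genes.

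Pirf, read as the anti-fibrotic drug pirfenidone, was compared with TGFb alone. ENSRNOG00000032832 fell from 505 ± 256 to 14.4 ± 6.88 normalized counts (log2 fold change -5.08, SE 0.42, adjusted p = 3.88e-11). ENSRNOG00000032626 fell from 2124 ± 1023 to 65.9 ± 25.4 (log2 fold change -4.98, SE 0.42, adjusted p = 4.99e-11). Both had risen from time 0 to 72 without treatment, by log2 fold changes of 3.52 and 3.13, and both lay below their time-0 means of 59.9 ± 24.8 and 466 ± 148 with Pirf. ENSRNOG00000026344 rose from 3.39 ± 5.15 to 60.7 ± 31.8 (log2 fold change 4.11, SE 0.82, adjusted p = 0.000101). ENSRNOG00000058438, which is outside the coding table, had 492 raw counts over the 6 Pirf libraries and 1 over the 6 with TGFb alone, a ratio of 426 with a counting interval of 76.1 to 16900 (adjusted p = 7e-04). Its normalized counts ranged from 3.31 to 157.7 among the Pirf libraries from 0 to 132.7 among the Nint libraries and from 0.888 to 202.6 among the Sora libraries. It was also called higher with Sora (adjusted p = 0.00401) and with Nint (adjusted p = 0.0293). The Nint call was lost without Nint replicate 3 or 5 or any one TGFb-alone library, and with the replicate number as a block. It was also lost in thinned libraries and against a fold of 1.2 (0.0531 to 0.105 over these settings).

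Pirf changed 8061 genes (51.5%), with 3926 higher and 4135 lower than with TGFb alone, and 1617 changed at least 2-fold. Without scaling factors 5973 rose and 2594 fell, and the median of all genes moved by 0.153 on the log2 scale. A test against a fold of 1.2 called 4099 genes.

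Nint, read as the kinase inhibitor nintedanib, changed far fewer genes against TGFb alone. ENSRNOG00000011946 fell from 120.7 ± 25.7 to 17.7 ± 7.19 normalized counts (log2 fold change -2.76, SE 0.31, adjusted p = 4.99e-07). ENSRNOG00000007475 fell from 303 ± 91.8 to 83.3 ± 18.5 (log2 fold change -1.87, SE 0.2, adjusted p = 4.15e-07). TGFb had moved these IDs in opposite directions, by log2 fold changes of 2.20 and -1.36. Neither fall was particular to Nint. Both IDs were also lower with Pirf (log2 fold changes -1.44 and -1.19, adjusted p = 9e-05 and 8.63e-06). With Sora the log2 fold changes were -2.46 and -1.81 (adjusted p = 9.78e-07 and 2.15e-07). ENSRNOG00000029514 rose from 449 ± 158 to 934 ± 140 (log2 fold change 1.06, SE 0.28, adjusted p = 0.0255), and its adjusted p passed 0.05 without Nint replicate 2 or 4 or TGFb-alone replicate 2 or 5, at 0.0628, 0.0579, 0.0849 and 0.0646, and was 0.14 against a fold of 1.2. ENSRNOG00000021260 rose from 53.5 ± 6.23 to 105 ± 20.3 (log2 fold change 0.97, SE 0.22, adjusted p = 0.00841), with an adjusted p of 0.095 in libraries thinned to one common total and 0.0569 against a fold of 1.2.

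The Nint comparison called 483 genes (3.09%), of which 138 rose and 345 fell, and 58 changed at least 2-fold. In a fit of its 12 libraries alone 298 rose and 330 fell. The number fell to 299 without TGFb-alone replicate 3 and 309 without TGFb-alone replicate 2, and was 99 against a fold of 1.2 and 779 with the scaling factor as a covariate.

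Sora, read as the kinase inhibitor sorafenib, lay between the other 2 drugs in the number of genes called. ENSRNOG00000025184 fell from 114.7 ± 35.9 to 8.11 ± 3.81 normalized counts (log2 fold change -3.83, SE 0.36, adjusted p = 1.37e-08). ENSRNOG00000011946 fell from 120.7 ± 25.7 to 21.8 ± 3.1 (log2 fold change -2.46, SE 0.3, adjusted p = 9.78e-07). ENSRNOG00000009342 rose from 19.6 ± 6.15 to 75.2 ± 23.6 (log2 fold change 1.94, SE 0.35, adjusted p = 0.00032). ENSRNOG00000050024 rose from 33.1 ± 36.8 to 146.7 ± 42 (log2 fold change 2.15, SE 0.68, adjusted p = 0.0293). That last call was lost with DESeq2 (adjusted p = 0.0786), in a fit of the 12 libraries alone (0.0838), against a fold of 1.2 (0.0954) and with the scaling factor as a covariate (0.143), and without TGFb-alone replicates 2, 4 or 6 or Sora replicates 1, 3 or 4 (0.0505 to 0.0705). TGFb had itself raised ENSRNOG00000009342 and ENSRNOG00000050024 (log2 fold changes 1.77 and 3.04, adjusted p = 0.002 and 0.00834), so Sora moved them further. With limma the TGFb call of ENSRNOG00000050024 was lost (adjusted p = 0.0733). The IDs that fell with Sora had also risen with TGFb, by log2 fold changes of 3.94 and 2.2.

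Sora changed 2406 genes (15.4%), with 1096 higher and 1310 lower, and 274 changed at least 2-fold. Without scaling factors 2173 rose and 684 fell, with a shift of 0.105 in the median of all genes on the log2 scale. The number was 1423 in a fit of the 12 libraries alone, 1470 with the scaling factor as a covariate and 410 against a fold of 1.2.

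**Figure D2:**
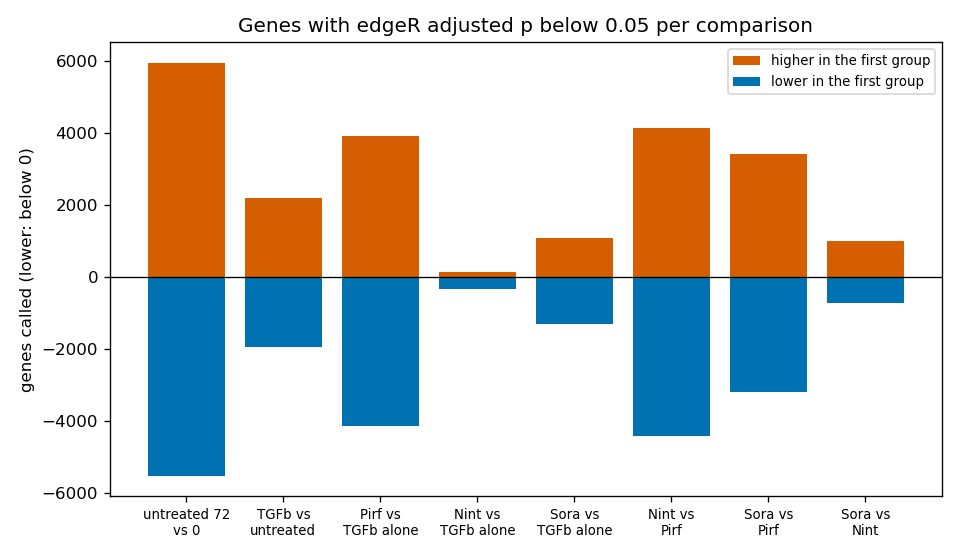
Bars give the number of genes called in each of the 8 comparisons (x axis), with genes higher in the first-named group above 0 and genes lower in it below 0 (y axis, number of genes). The comparison over time called 5938 and 5516 genes, and Nint against TGFb alone 138 and 345.

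The drugs were then compared directly, at doses that the labels do not give. Nint and Pirf differed in 8544 genes, 4140 higher and 4404 lower with Nint (2660 and 6258 without scaling factors, with a median shift of -0.165 on the log2 scale). Sora and Pirf differed in 6592 genes, 3414 higher and 3178 lower with Sora (2715 and 3686 without scaling factors). Sora and Nint differed in 1720 genes, 1006 higher and 714 lower with Sora (2148 and 432 without scaling factors, with a median shift of 0.121). This last number was 942 without Sora replicate 4, 974 without replicate 3, 990 without replicate 2, 996 without replicate 1 and 2819 without replicate 5. It was 1057 without Nint replicate 5, 1096 without replicate 3, 1111 without replicate 1, and 451 with the scaling factor as a covariate.

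Whether the drugs moved the TGFb genes back was asked next. Among the genes reversed by all 3 drugs, the 2 with the largest rise and the 2 with the largest fall after TGFb are given. ENSRNOG00000025184 stood at 7.38 ± 2.22 normalized counts in untreated slices and 114.7 ± 35.9 with TGFb, and at 23 ± 10, 38.9 ± 7.86 and 8.11 ± 3.81 with Pirf, Nint and Sora (adjusted p = 7.46e-07, 0.00309 and 1.37e-08 against TGFb alone). ENSRNOG00000020525 stood at 365 ± 83.4 and 4127 ± 628, and at 1617 ± 277, 2156 ± 445 and 798 ± 134 with the drugs in the same order. ENSRNOG00000047123 fell with TGFb from 33 ± 2.65 to 8.99 ± 1.66 and stood at 39 ± 6.9, 16.5 ± 3.5 and 21.7 ± 7.87 with the drugs. ENSRNOG00000004276 fell from 6067 ± 627 to 2175 ± 329 and stood at 3610.2 ± 979, 3720.4 ± 452 and 4152 ± 1128, and its lowest Pirf library (2117) and lowest Sora library (2397) lay below the highest with TGFb alone (2603). For Nint the adjusted p of ENSRNOG00000020525 was 0.0266 and that of ENSRNOG00000047123 was 0.018. The first passed 0.05 without Nint replicate 1, 3 or 5 or TGFb-alone replicate 3 or 5 (0.0525 to 0.0825), and the second without Nint replicate 2 or 4 (0.058 and 0.0515) and in thinned libraries (0.14). Against a fold of 1.2 both Nint calls were lost (0.154 and 0.122), and with them the reversal by all 3 drugs.

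**Figure D3:**
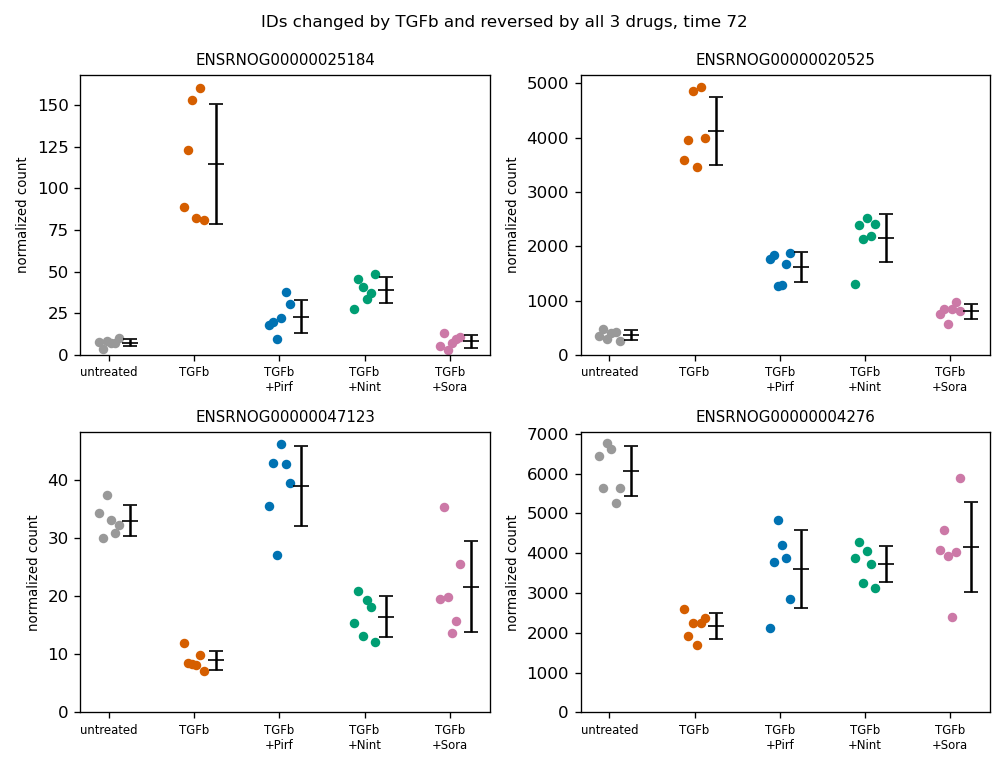
Each panel shows one of the 4 IDs reversed by all 3 drugs, with normalized counts (y axis, from 0) of the 6 libraries in each of the 5 groups at time 72 (x axis). Points are libraries and black bars are the mean ± SD. All 6 TGFb libraries of ENSRNOG00000020525 lie above 3451, and all 6 with Sora lie at 972 or below.

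Of the 4130 TGFb genes, Pirf reversed 1846 (44.7%) and moved 542 further in the TGFb direction. Sora reversed 1113 (26.9%) and moved 63 further. Nint reversed 165 (4%) and moved 108 further. Independent lists of these sizes would give 1070, 319 and 65.4 reversed genes for Pirf, Sora and Nint, and 1060, 316 and 62.1 moved further. Nint thus exceeded independent lists in both directions, and Pirf and Sora only in reversal. At least 1 drug reversed 2259 genes (54.7%), and all 3 reversed 70, of which 30 had risen and 40 had fallen with TGFb. The number reversed by Nint was 92 without TGFb-alone replicate 2, 107 without TGFb-alone replicate 5, and 107, 105, 96 and 107 without Nint replicates 1, 2, 4 and 5. The number reversed by all 3 was 44 without TGFb-alone replicate 2 and 45 without Nint replicate 2 or 4. Pirf alone reversed 596 risen and 514 fallen genes, and Pirf and Sora without Nint reversed 368 risen and 292 fallen genes. Among genes that TGFb raised at least 2-fold, Pirf reversed 50.3%, Sora 39.6% and Nint 5.05%. Among those it lowered at least 2-fold, the shares were 42%, 31.8% and 5.65%.

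The TGFb-alone libraries are shared by these comparisons, and simulations without any drug effect gave means of 17.7 reversed genes for Pirf, 54 for Sora and 0 for Nint, for which edgeR called no gene in any simulation, with highest values of 354 for Pirf and 1079 for Sora. Both means rest on 1 of the 20 simulations, since the others called no gene for any drug. The drug groups were simulated alike, so the 0 is not particular to Nint, and both highest values exceed the 165 genes that Nint reversed. The covariance of log2 fold changes across genes, which are not independent replicates, was -0.171 between TGFb and Pirf, against a simulated mean of -0.0592. It was -0.135 for Sora, against -0.0494. Single simulations reached -0.186 and -0.159, so both observed values lay within the simulated range. For Nint it was -0.0442, against -0.0552, so that the observed value did not exceed the simulated one. Observed correlations across genes were -0.385, -0.552 and -0.216, where TGFb was compared with Pirf, Sora and Nint, and simulated means were -0.27, -0.21 and -0.24. The lowest simulated correlations were -0.507 for Sora and -0.562 for Pirf. Since the drug groups were simulated alike, all 3 observed correlations lay within the simulated range. With the TGFb-alone libraries split into 3 and 3, reversed genes averaged 1100 for Pirf (875 to 1489) and 489 for Sora (342 to 656), against 344 and 45.6 moved further. For Nint they averaged 45.3 (21 to 135), against 58.3 moved further (12 to 231) and 24 from independent lists, and which of the first 2 was larger varied between splits, and the mean covariance was 0.00462.

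In libraries not used to choose the genes, Pirf removed 33.1% ± 9.9 (SD, n = 6) of the mean TGFb change, Sora 34.7% ± 8.34 and Nint 11.1% ± 5.09. Pirf exceeded Nint by 22 percentage points and Sora exceeded Nint by 23.6 (exact permutation p = 0.0022 for each, the smallest that 6 against 6 libraries allow, adjusted p = 0.0033 over 3 tests). Each of the 6 Pirf and 6 Sora libraries, at 21.2% or more, lay above the highest Nint library at 18.9%. Pirf and Sora differed by -1.55 percentage points (exact permutation p = 0.77), which the spread between libraries does not resolve. Like shares need not mean like patterns, since the share is a mean over genes, and Pirf moved 542 TGFb genes further and Sora 63. The share depended on which libraries were held out, ranging from 10.3% to 54.6% for Pirf, 22.5% to 41.3% for Sora and -1.64% to 19.2% for Nint over the 40 choices. All drug libraries were measured against the same TGFb-alone libraries, whose spread the SD leaves out. No simulation without a drug effect was run for the share, so whether Nint removed any of the TGFb change was not tested. For genes that rose the means were 37%, 34.1% and 11.7% for Pirf, Sora and Nint, and for genes that fell 29.2%, 35.3% and 10.5%.

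**Figure D4:**
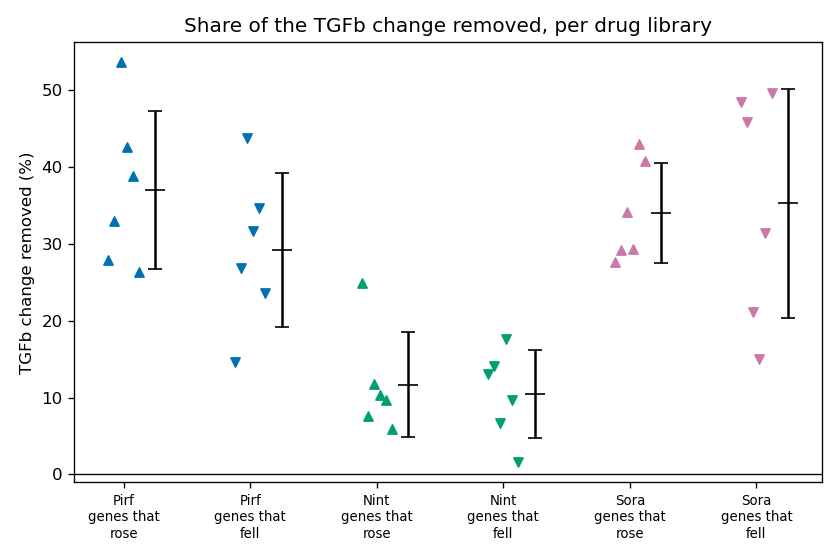
Points give the percentage of the mean TGFb change removed (y axis) in each drug library, for genes that TGFb raised and lowered (x axis), averaged over 40 choices of held-out libraries, and black bars are the mean ± SD of 6 libraries. Values for genes that rose lay between 26.4% and 53.6% with Pirf and between 5.91% and 24.9% with Nint.

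The drug responses were also compared with each other. Pirf and Sora moved 1513 genes in the same direction and 111 in opposite directions, where independent lists give 275 shared rises and 346 shared falls against 644 and 869 observed. The covariance was 0.163, against a simulated mean of 0.0516 from the shared TGFb-alone libraries, and averaged 0.123 (0.0732 to 0.177) with these libraries split. Nint and Sora moved 242 genes in the same direction, with a covariance of 0.0477 against a simulated 0.0554 and a mean of -0.00343 with split libraries. With split libraries, 62.2 genes on average (45 to 124) moved in the same direction and 7.75 (0 to 109) in opposite directions. Pirf and Nint moved 134 genes in the same direction and 121 in opposite directions, with a covariance of 0.015 against a simulated 0.0512 and a mean of -0.0357 with split libraries. With split libraries, 40 genes on average (23 to 80) moved in the same direction and 66.6 (8 to 390) in opposite directions. Which of these was larger varied between splits, and the covariance ran from -0.134 to 0.0529.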

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

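The rule for a library that stands apart from the other 5 of its group was fixed before the data were examined, and no explanation was tested for the single libraries it picked out. It was applied to 99 groups of values, of which 7 held such a library. Chance picks out about 1 group in 20.

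On the second principal component, Nint replicate 5 scored -12.83, whereas the other 5 Nint libraries scored -30.15 to -25.56. Untreated replicate 3 at time 0 held 13.4 normalized counts of ENSRNOG00000007509, against 0 to 3.19 in the other 5, and 109.9 of ENSRNOG00000006926, against 4.64 to 11. Both IDs rose from time 0 to 72, and the same library lay nearest to the later levels in both. Untreated replicate 1 at time 0 held 6733.98 normalized counts of ENSRNOG00000019500, which fell from time 0 to 72, against 16653.5 to 22602.2 in the other 5. TGFb-alone replicate 3 held 2679.5 normalized counts of ENSRNOG00000011824, against 774.6 to 1101. TGFb-alone replicate 1 held 1.08 of ENSRNOG00000058438, which is a single count, against 0 in the other 5. Nint replicate 1 held 1298 of ENSRNOG00000020525, against 2130 to 2514, and thus lay farther from TGFb alone than the other 5.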

How the results depend on the processing

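The scaling factor as a covariate, total counts without scaling factors, thinning, and the time-0 comparison without replicates 1 and 3 were chosen after the data were examined. With DESeq2 size factors, the stricter filter, the coding table alone, limma on the deposited log2 CPM, thinned libraries or no scaling factors, the 8 numbers of called genes and the 4 of reversed genes stayed within 1.5 times their values. In 0 of 15 group pairs did the deviations from group means of all same-numbered libraries correlate above 0.1. These correlations averaged 0.017 for the same number and -0.003 for other numbers. Pairing of only some libraries is not excluded by this criterion. A replicate block gave 4243 TGFb, 8121 Pirf, 487 Nint and 2602 Sora genes, and 2047 between Sora and Nint. For the changes that follow, the cause was not tested unless given. Without a filter, Sora and Nint differed in 1133 genes. In fits of 12 libraries Sora changed 1423 genes and Nint reversed 259, and with DESeq2's test Nint reversed 260. Against a fold of 1.2, a stricter hypothesis, the numbers were 1779 (TGFb), 4099 (Pirf), 99 (Nint), 410 (Sora), 4602 (Nint against Pirf), 2520 (Sora against Pirf) and 186 (Sora against Nint), with 622, 19 and 257 reversed by Pirf, Nint and Sora and 7 by all 3, while 9038 genes still changed from time 0 to 72. The covariate gave 779 Nint and 1470 Sora genes, 451 between Sora and Nint, and 333 reversed by Nint and 112 by all 3. It also gave 5526 Pirf genes, of which 4221 were among the 8061 called without it. With replicates 1 to 3 of TGFb alone for TGFb and 4 to 6 for the drug, and so with fewer libraries, 949, 36 and 656 genes were reversed by Pirf, Nint and Sora. The opposite split gave 56 for Nint and 342 for Sora, and the other splits gave as few as 875, 21 and 366, and as many as 632 for Sora. Leaving out single libraries gave 299 (without TGFb-alone replicate 3) to 572 Nint genes, with 309 without TGFb-alone replicate 2. Sora and Nint differed in 942 to 2819 genes, without Sora replicates 4 and 5, with 996, 990 and 974 without Sora replicates 1, 2 and 3 and 1111, 1096 and 1057 without Nint replicates 1, 3 and 5. Nint reversed 92 (without TGFb-alone replicate 2) to 194 genes, with 107 without TGFb-alone replicate 5 and 107, 105, 96 and 107 without Nint replicates 1, 2, 4 and 5. All 3 drugs reversed 44 (without TGFb-alone replicate 2) to 86, with 45 without Nint replicate 2 or 4. Of 1265 values of the named IDs under other settings, by edgeR, DESeq2 or limma, 1220 were counted as unchanged, 32 lost the call and 13 gained one. Of the results called in the main fit, 0 changed direction. Results not called in the main fit were counted as unchanged even where their direction changed. In a separate set of values, each with a single library left out, 1228 were counted as unchanged by the same rule, 44 lost the call and 12 gained one. The alternatives for gene lists were not run, since no ID could be paired with a name. Depth limited the calls modestly: in thinned libraries 3774 genes were called for TGFb, 7560 for Pirf, 422 for Nint and 2168 for Sora.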

Other observations

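The tests of RNA composition were chosen after the results they concern were seen, and so were the comparisons with untreated slices and of genes by their change over time.

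Random regroupings of the same libraries were used to ask whether chance could give as many genes. For the number of called genes, 100 splits of the 12 libraries of each comparison were fitted, the real one included. The real split was the only 1 to reach its count from time 0 to 72 (10530 genes, next 4177), for TGFb (3789, next 485), Pirf (8302, next 3279), Nint against Pirf (9452, next 3559) and Sora against Pirf (6840, next 846). As many genes came from 2 of the 100 splits, the real one included, for Nint (628, other 1671), Sora (1423, other 4478) and Sora against Nint (1661, other 2297). Reversed genes were counted in fits of only the untreated and TGFb-treated libraries concerned, so the real counts here differ from those of the fit of all 36 libraries (1846, 165, 1113 and 70). Of 100 regroupings, 3 gave as many genes reversed by Pirf (2148, highest other 3037), 2 as many reversed by Nint (336, highest other 506) and 2 as many reversed by Sora (1039, highest other 2443). For genes reversed by all 3 drugs, 1 of 60 did so (142, highest other 0). In these fits, a random grouping of the libraries is thus excluded at the 0.05 level as the source of each number of called genes. The reversed counts passed the same level, but their regroupings mixed libraries of groups that differ in called genes. Such mixing can widen the spread within a group and lower its counts. The real grouping can then rank high merely because the groups differ, which does not decide whether the reversal arose by chance. These regroupings also keep the TGFb-alone group shared between comparisons, so they do not show that any drug reverses TGFb genes. The 3037 genes came from a regrouping in which TGFb-alone replicates 1, 2, 4, 5 and 6 stood in the Pirf group. With the TGFb-alone libraries split, reversed genes averaged 1100 for Pirf and 489 for Sora, against 344 and 45.6 moved further. For Nint they averaged 45.3, against 58.3 moved further, and which was larger varied between splits. The median of the other splits was 0 for each comparison and each reversal count. For Nint and Sora 1 other split each nevertheless called more genes than the real one (1671 and 4478), which points to a structure of the samples that the groups do not explain.

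Differences between libraries of one group were examined first. After group means were removed, one component held 19.3% of the variance between libraries. It was not shown to be the structure behind those splits. TGFb-alone replicates 3 and 5, on one side of the Nint split, scored -26 and 39.2 on it. TGFb-alone replicates 1 and 5, on one side of the Sora split, scored -24.8 and 39.2. The tests of this component therefore do not decide what made those splits differ. Replicate number explained 34.6% of the component's variance (permutation p = 0.02, adjusted p = 0.08 over 4 properties), which failed the correction. It explained no more than 39.6% with any one library left out, so it could account for only a part. Plate row explained 7.77%, plate column 11.6% and total count 0.181%. The correlation with total count was 0.04 (Pearson, permutation p = 0.81) and 0.1 (Spearman, permutation p = 0.56), and Pearson's r was 0.12 without the 2 libraries farthest from the median. The splits that called most genes for Nint and for Sora parted the libraries by scaling factor more than 99.8% and 99.8% of the 462 possible splits. A difference in RNA composition between libraries of one group is therefore a candidate explanation. Its origin, such as the tissue taken for each slice or the handling of the RNA, was not tested. It need not hold for every comparison, since the highest other split for Sora against Pirf exceeded only 6.49% of splits in that gap. The real splits exceeded 99.8% of splits for Pirf, 96.5% for Sora and 9.96% for Nint, so for Pirf and Sora composition and treatment went together.

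Genes that rose without treatment from time 0 to 72 tended to be lower with Pirf than with TGFb alone, and the reverse. Pirf lowered 40.6% and raised 15.8% of the 5938 genes that had risen, and raised 33.3% and lowered 16.4% of the 5516 that had fallen. In all, 4246 genes moved in opposite directions and 1847 in the same direction. Sora showed this to a smaller extent, with 1193 genes in opposite directions and 643 in the same, and a covariance of -0.0663. In 20 simulations without drug effects the drug groups were simulated alike. The lowest simulated covariances were -0.0523 for Sora and -0.0758 for Pirf, so the observed value for Sora lay within the simulated range. No library is shared by the comparison over time and those of the drugs. For Pirf, r across genes, which are not independent replicates, was -0.317. Of the 462 splits of the Pirf and TGFb-alone libraries, 1, the real one, gave a covariance as far from 0 (-0.202, next 0.161 in size), computed here from differences in mean log2 CPM and not from edgeR's fold changes, which argues against library structure unrelated to the groups. The correlation was -0.328 in the genes with the higher expression and -0.314 in the others, against an origin in low counts. The covariance of edgeR's fold changes was -0.275 with thinned libraries and -0.274 for the same genes before thinning, against an origin in depth. An effect of Pirf on the change that slices undergo over time may account for its part of the pattern, a hypothesis found and tested on the same data. RNA composition, which went together with Pirf, stays open, and so do gene length and GC content, which were not tested. Of the TGFb genes that had also moved in the same direction over time, Pirf reversed 52.6% of 1984, against 33.2% of 1161 that had moved in the opposite direction. For Sora these shares were 27% and 26.6%, and for Nint 1.86% and 6.29%. The difference between the drugs in these shares was not tested.

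Pirf changed 16.7 times as many genes as Nint, with 8061 and 483 called. The size of this ratio varied: the numbers were 8230 and 299 without TGFb-alone replicate 3, 7828 and 309 without TGFb-alone replicate 2, 5526 and 779 with the scaling factor as a covariate, and 4099 and 99 against a fold of 1.2. With thinned libraries the ratio was 17.9, which argues against depth. The median SD within the Nint group was 1.08 times that within the Pirf group, which argues against a larger spread among Nint libraries. The main fit also pooled each gene's spread over all groups, and the median SE was 0.116 in both comparisons. A larger spread in the Nint group alone would thus weigh on both numbers there. What the spread of the TGFb-alone libraries, which enter both comparisons, contributes stays open. The labels give no doses, so a difference in dose stays open as an explanation that was not tested.

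Compared with untreated slices at 72, slices with TGFb and a drug differed in 8131 genes for Pirf, 4137 for Nint and 3913 for Sora. These comparisons share the untreated libraries with the TGFb comparison, so the overlap of their genes with the TGFb genes was not read as a measure of what the drugs left in place.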
